A study of Homo sapiens with 12 samples.

How the data were processed

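Total RNA from cells labelled C4-2B/Rx2dox, a prostate cancer line with a doxycycline-inducible RUNX2 gene, was labelled with biotin and hybridised to single-colour Illumina BeadChips, per the labels. The cells were grown in medium with 10% FBS and then kept in phenol-red-free medium with 5% charcoal-stripped serum for 48 h before treatment with ethanol vehicle, dox, DHT or both. The doses are given as the labels state them (DHT 10 mM, dox 250 µg/ml for 48 h). They are far above those commonly used with cultured cells, and the unit was not resolved here. The design was described as biological triplicates, so that 12 arrays fell into 4 groups of 3 by the treatment stated in the labels. No group was taken from the values.

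The deposited values were linear probe intensities made with GenomeStudio, per the submitters' processing notes, and the version was not given in the sources used here. Neither the normalization nor the background step was given in the sources used here. The columns shared their quantiles: sorted columns differed by 0.8 intensity units at most, and every array ran from 84.1 to 27321.9 with a median of 137.6. Since no value lay near 0, the intensities still held background signal, which compresses the fold changes of dim probes. All 12 columns were used and 0 values were missing.

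The value table held 47230 probes. A table of probe genes gave 30113 of them a single gene symbol and 8 several symbols, and left 17109 unnamed. Of the probes with a single symbol, 30074 were named through their gene identifier in the RefSeq gene table of the human assembly GRCh38.p14, which was used only for names, and 39 kept the platform's symbol. Named probes covered 20047 genes, and probes without a name or with several entered no comparison of genes. Unnamed probes were tested separately and are given only as counts.

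Because the quantiles already matched, the intensities were used without further normalization, with a floor of 20 (0 values lay below it) and then log2. The background limit was the 95th percentile, over all arrays, of 629 probes for 527 genes of the olfactory receptor, keratin-associated protein, taste receptor and defensin families. It was 147.6 intensity units (log2 7.2052), and the median of these probes was 118.5. A probe was taken as above background in a group when its mean there was above the limit, and 42.2% of all probes were above it on each array. Genes with a probe above background in at least 1 group were tested, each by its probe with the highest mean over all arrays, which left 12118 genes. Where a gene was not above background on any array of a group, its fold was given as a bound ("at least"): the brighter group's mean over the dimmer group's mean of, per array, the higher of the limit and the probe's own value, as means of log2 values. Among 3227 genes with several such probes, 15 had probes called in opposite directions in dox against vehicle and 2 in DHT against vehicle.

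One linear model with 4 group means was fitted to all arrays with limma 3.58.1 (lmFit, then eBayes with a trend in the prior variance) in R 4.3.3, so that the groups shared 1 estimate of the spread per gene. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. The comparisons were dox against vehicle, DHT against vehicle, DHT with dox against DHT, against dox and against vehicle, and the interaction, which is the DHT change with dox minus that without it. The two-sided p-values were adjusted by the Benjamini-Hochberg method over the genes tested, with a threshold of 0.05, and counts were also made with a change of at least 1.5-fold. Genes called androgen-responsive passed the test for the average of the DHT changes without and with dox, which in a balanced design does not lean on the interaction. Among them, an interaction opposite in sign to the average change was counted as attenuation, and one of like sign as augmentation.

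Before the data were examined, the tests, alternatives, rule for named genes and 22 gene lists were fixed. The lists covered androgen-induced, androgen-repressed, androgen coregulator, RUNX2 skeletal and invasion, mesenchymal transition, epithelial junction, secreted protease, cell cycle, cholesterol and fatty acid synthesis, unfolded protein response, amino acid and mitochondrial stress, interferon, p53, polyamine, Wnt with TGF-beta and BMP feedback, hypoxia and glycolysis, and housekeeping genes. They also covered neuroendocrine, basal prostate, fibroblast, immune and endothelial markers. The androgen coregulator list was mixed. Beside coregulators it held steroid enzyme genes such as AKR1C3 and HSD17B4, and other transcription factor genes such as SPDEF and NR3C1. Lists were tested with camera at a preset correlation of 0.01, with an estimated correlation, and with fry, and adjusted over the lists within a comparison. Another 5 lists (estrogen-induced genes, the part of them and the estrogen-repressed genes not seen beforehand, and luminal markers of breast and prostate) were written after the first results were seen and were adjusted apart.

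The genes named were RUNX2 on every array, then for each comparison the 10 largest rises and 10 largest falls past the threshold whose replicates did not overlap between the groups. For the interaction they were the 10 most positive and 10 most negative calls, and the same among androgen-responsive genes. Up to 4 members of each list with the smallest p, and KLK3, TMPRSS2, FKBP5 and SNAI2, were also named, and 2 other genes fixed beforehand are not reported here. Transcripts without a known product were left unnamed in places. Other genes are stated to have been chosen after their values were seen.

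The fit was tested on simulated data over 12118 genes, with the vehicle means in all groups and independent noise of the real spread. In each run 80 genes were changed by 0.5 on the log2 scale, 80 by 1 and 40 by 1.5. These are far fewer than were called in dox against vehicle, so the shares and false calls hold only for such data. For dox against vehicle the fit recovered 75% of genes changed by 0.5 on the log2 scale and 100% of those changed by 1, with 10 false calls. For DHT against vehicle the shares were 80% and 100% with 12 false calls, and for the interaction 48.8% and 92.5% with 8 false calls.

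The alternatives tried were quantile normalization applied again, arrays shifted to a common median, a floor of 10, an offset of 50, no filter or a stricter filter on dim probes, the mean of a gene's probes, and every probe tested. Others were no trend in the prior variance, array weights, only the groups compared, the replicate number as a block, an adjusted p under 0.01, and other choices of androgen-responsive genes. Each array was also left out in turn. Subtraction of the background median was added after the data had been seen. Groups were also compared over all 10 splits of 6 arrays. For the average DHT change 100 regroupings of the arrays were drawn, and for the interaction 100 reassignments of the residuals around a fit without it, the real one included in each.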

Results

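Genome-wide expression was measured on 12 single-colour bead arrays, each hybridised with biotin-labelled RNA from one culture. The labels describe C4-2B prostate cancer cells in which doxycycline (dox) switches on RUNX2, the transcription factor that drives bone formation. The cultures fell into 4 groups of 3 arrays in a factorial design: vehicle, dox, the androgen dihydrotestosterone (DHT), and DHT with dox. Per the labels, DHT was given at 10 mM and dox at 250 µg/ml for 48 h. The table held 47230 probes, of which 30113 carried a single gene symbol, and 12118 genes lay above the background limit in at least 1 group. Across all probes, named or not, with a mean over all arrays above the limit, replicate arrays of a group correlated at 0.9938 to 0.9954. Arrays of different groups correlated at 0.9767 to 0.9932. The first principal component held 59.7% of the variance and parted the arrays labelled dox from the others, and the second held 12.3% and parted the arrays labelled DHT. The number of arrays limits the precision of every comparison.

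RUNX2, the gene that dox was meant to induce, was examined first on every array. Its brighter probe (ILMN_1716651) read 210.3, 206.8 and 225.8 on the vehicle arrays and 293.1, 271.7 and 244.6 on the arrays labelled dox. It read 313.0, 273.9 and 270.9 on the arrays labelled DHT, and 331.1, 258.6 and 321.9 on those labelled DHT with dox. Against vehicle, the log2 fold change was 0.33 ± 0.10 (SE, n = 3 per group) for dox and 0.41 for DHT, with limma adjusted p of 0.016 and 0.0148. In arrays labelled DHT with dox against DHT alone it was 0.08 (limma adjusted p = 0.578). The second RUNX2 probe (ILMN_2377746) averaged 169.3 ± 9.57 (SD, n = 3) on vehicle arrays and 168.0 ± 11.7 on dox arrays. The rise against vehicle lost its call without vehicle replicate 2 (0.30 for dox and 0.39 for DHT), without dox replicate 1 (0.27) and without DHT replicate 1 (0.35). With the mean of both probes it was 0.16 for dox and 0.17 for DHT, at limma adjusted p of 0.149 and 0.239. The transcript regions that these probes read, and whether an induced RUNX2 copy holds them, are not given in the sources used here, so the probes check nothing of an induced copy and leave the dox label unchecked.

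The levels of lineage genes went against the labelled cell line, and were examined after the values had been seen. KLK3, which encodes prostate-specific antigen, was above the background limit of 147.6 on 1 of 12 arrays, with a highest intensity of 178.6. KLK2 and the prostate membrane antigen gene FOLH1 were above it on 0 arrays, and the prostate homeobox gene HOXB13 on 1. The estrogen receptor gene ESR1 read between 2157 and 4711 on all 12 arrays, the luminal transcription factor gene GATA3 between 2472 and 4562, and the trefoil factor gene TFF1 between 6293 and 22780. FOXA1, a pioneer factor of both tissues, read between 6586 and 10059. Of 18 prostate luminal markers with a probe, 3 (PMEPA1, SLC45A3 and MSMB) were above the limit on all arrays, against 12 of 14 breast luminal markers. The breast markers SCGB2A2 and ANKRD30A were above it on 0 arrays. Among the lists fixed beforehand, 0 of 8 endothelial, 3 of 11 immune, 6 of 12 fibroblast, 3 of 12 neuroendocrine and 4 of 8 basal epithelial markers were above background in at least 1 group. All comparisons below therefore refer to arrays by their labels, and a direction drawn from a label holds only as far as that label does.

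**Figure D1:**
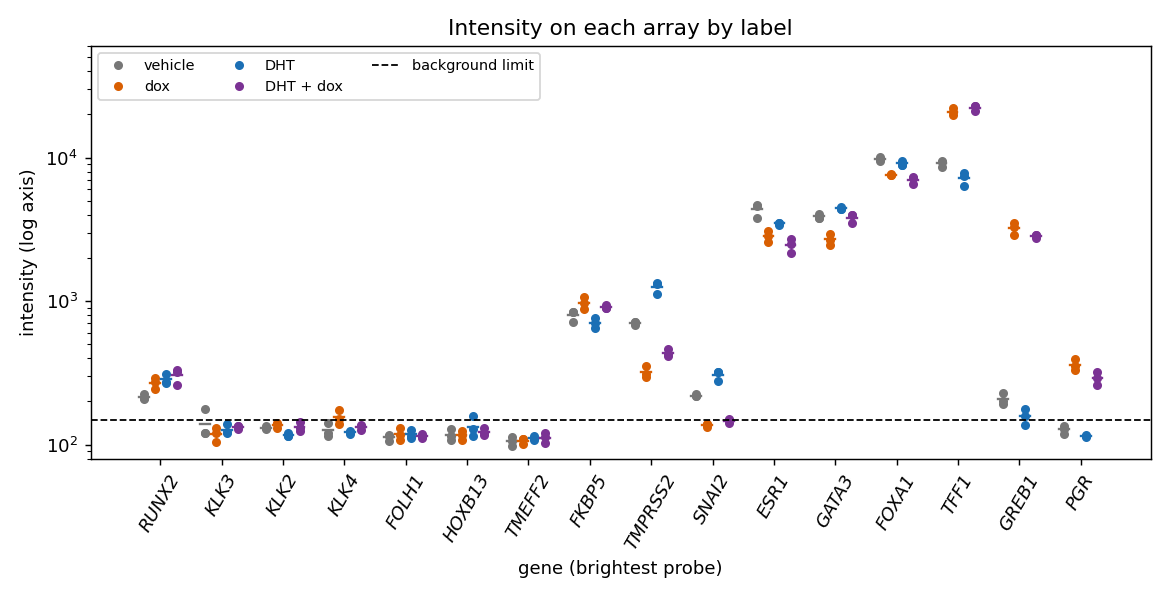
Intensity of 16 genes on each of the 12 arrays (log axis, brightest probe of each gene), with points coloured by label, short lines at group means and a dashed line at the background limit of 147.6. KLK2, FOLH1 and TMEFF2 lie below the dashed line on every array and KLK3 on all but 1, while ESR1, GATA3, FOXA1 and TFF1 lie far above it on all arrays.

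The first comparison, dox against vehicle, was meant by its labels to show what RUNX2 induction changes without androgen. GREB1, a cofactor of the estrogen receptor, was 15.5-fold higher on the arrays labelled dox (log2 3.96 ± 0.10 SE, n = 3 per group, limma adjusted p = 1.72e-17), at a mean intensity of 3216 against 207.3. Its other 3 probes lay near the background limit and changed by 0.36, 0.25 and 0.38. MGP, an inhibitor of calcification, was 9.49-fold higher, the kallikrein gene KLK11 7.09-fold and the Notch target HEY2 6.33-fold. ARHGAP36, above the limit on 1 of 3 vehicle arrays, was 7.16-fold higher, IGSF1 6.09-fold, the protease gene PRSS23 5.11-fold and PKIB 4.88-fold, while the kinase gene SGK1 was 4.73-fold and the proto-oncogene MYB 4.62-fold higher. In the other direction UPK1A, a urothelial membrane protein gene, was 6.01-fold lower, BCAS1 4.66-fold and IGFBP3, which binds insulin-like growth factors, 4.45-fold lower. TNS3, a gene of focal adhesions, was 3.48-fold lower, and the p53 target TP53INP1 3.36-fold. The epithelial transcription factor gene GRHL3 (3.25-fold), the lipocalin gene APOD (3.18-fold), the growth factor antagonist gene SPRY1 (3.06-fold), P2RX2 (2.91-fold) and HCAR1 (2.88-fold) were also lower.

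Of the 12118 genes tested, 3978 passed limma's adjusted p of 0.05, with 1951 higher and 2027 lower on the arrays labelled dox, and 733 of them changed at least 1.5-fold. Cell cycle genes rose together: 28 of 31 measured members were higher and 3 were not called (28 adjusted over the list alone), with CDC20 up by 0.62, CDC45 by 0.66, BIRC5 by 0.62 and CCND1 by 0.60 on the log2 scale. The camera test gave this list an adjusted p of 8.01e-14, and 0.00558 with an estimated correlation. Of 19 amino acid and mitochondrial stress genes, 9 rose and 1 fell (12 and 2 adjusted over the list alone), led by the amino acid transporter genes SLC7A5 (1.79) and SLC3A2 (1.18), with DDIT4 at -0.87. Its camera adjusted p was 0.00185, and 0.0489 with an estimated correlation. Among 9 polyamine synthesis genes 5 rose and 1 fell (6 and 1 adjusted over the list alone), AMD1 by 0.89 and ODC1 by 0.60, while SAT1, which breaks polyamines down, was at -0.81. Among 16 Wnt, TGF-beta and BMP feedback genes 10 fell and 1 rose (10 and 1 adjusted over the list alone), with ID1 at -1.26, BAMBI at -1.13 and ID3 at -1.08. Of 11 members of the androgen coregulator list, 7 fell and 4 were not called (7 adjusted over the list alone). Those that fell included TLE1 (-0.77), the enzyme gene HSD17B4 (-0.51) and FOXA1 (-0.35). These last 3 lists passed camera at adjusted p of 0.0301, 0.000334 and 0.00157, but gave adjusted p = 0.0982, 0.0536 and 0.0956 with an estimated correlation.

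Members of other lists moved both ways. Of 26 androgen-induced genes 5 rose and 9 fell (5 and 10 adjusted over the list alone), with SGK1 up by 2.24 and TSC22D3, TMPRSS2 and ALDH1A3 at log2 fold changes of -1.38, -1.14 and -1.07. FKBP5, a classical androgen and glucocorticoid target, was 1.23-fold higher (limma adjusted p = 0.0132), a call lost without vehicle replicate 2 (log2 0.21, adjusted p = 0.0919) or dox replicate 2 (0.23, adjusted p = 0.0796). Of 8 androgen-repressed genes 2 rose and 3 fell (the same counts adjusted over the list alone). UGT2B17 and UGT2B15, not above background on the vehicle arrays, were at least 1.77-fold and at least 1.22-fold higher, and the chemokine receptor gene ACKR3 changed by -1.23. The RUNX2 skeletal and invasion list had 3 rising and 3 falling among 15 (the same counts adjusted over the list alone), with CXCL12 up by 2.06, SOX9 at -1.03 and SMAD3 at -0.74. Its median log2 change was -0.083 and its mean 0.014, and camera pointed down (adjusted p = 0.8). SPP1 stayed near background. SNAI2, a repressor of epithelial genes, was at least 1.49-fold lower by its brightest probe, which was not above background on the arrays labelled dox, and its other probe, above it on 1 of these 3 arrays, changed by -0.50. CD44 rose by 0.81 and TGFBI changed by -0.77 among 9 mesenchymal transition genes, of which 2 rose and 2 fell (2 and 3 adjusted over the list alone). Epithelial junction genes (3 rose and 6 fell of 19), hypoxia and glycolysis genes (3 and 7 of 18), p53 targets (5 and 3 of 16, median 0.003, mean -0.072), interferon response genes (1 and 4 of 22), and cholesterol and fatty acid synthesis genes (3 and 6 of 19) did not pass camera. Adjusted over the list alone these counts were the same, except for 8 falling hypoxia genes. Nor did secreted proteases (2 and 4 of 13, with CTSD up by 1.01) or unfolded protein response genes (5 and 2 of 17, with XBP1 up by 0.92). Of the 3 neuroendocrine markers measured, ENO2 rose by 0.52 and STMN1 by 0.44. The basal markers ITGB4 and LAMB3 changed by -0.47 and 0.23, and LAMB3 lost its call without any 1 vehicle array, dox replicate 1 or 3, or DHT replicate 3, at limma adjusted p between 0.0505 and 0.145, and with the replicate block (0.0568), no filter on dim probes (0.0805) or only the groups compared (0.0534). Of 6 fibroblast markers TAGLN changed by -0.28 (-0.24 and adjusted p = 0.0624 without vehicle replicate 2), and limma called 0 of 3 immune markers (0 at an unadjusted p under 0.05). Of 16 housekeeping genes 4 rose, TUBB and HPRT1 by 0.47 each, and 2 fell.

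The same contrast in the presence of DHT (DHT with dox against DHT) was meant to show what RUNX2 induction changes in androgen-treated cells. GREB1 was 18.0-fold higher on the arrays labelled DHT with dox (log2 4.17 ± 0.10 SE, n = 3 per group, limma adjusted p = 1.19e-17), and above background on 2 of 3 arrays labelled DHT. MGP was 7.01-fold, HEY2 6.46-fold, PKIB 5.50-fold and KLK11 5.37-fold higher, followed by MYB (4.48-fold), PRSS23 (4.02-fold) and the receptor activity modifier gene RAMP3 (3.98-fold). KLK11 and RAMP3 were above background on 1 of 3 arrays labelled DHT. UPK1A was 6.20-fold lower, BCAS1 4.64-fold, and EPAS1, which encodes a hypoxia-inducible factor, 4.26-fold. HCAR1 was 4.17-fold lower, and APOD changed by -2.00 on the log2 scale. The adaptor gene DAB2 was 3.62-fold lower (above background on 1 of 3 arrays labelled DHT with dox), the immune checkpoint ligand gene VTCN1 3.49-fold and EFHD1 3.45-fold. TMPRSS2 was 2.88-fold, and SNAI2 2.07-fold lower, with 2 of 3 arrays of the DHT with dox group above background for SNAI2. FKBP5 was higher by 0.38 on the log2 scale.

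In this comparison 4068 genes passed the test, 1736 higher and 2332 lower, and 746 changed at least 1.5-fold. Cell cycle genes rose again, 27 of 31 with 4 not called (30 adjusted over the list alone), and AURKB was up by 0.76 (camera adjusted p = 3.2e-13, and 0.00649 with an estimated correlation). Of 11 members of the androgen coregulator list 8 fell and 3 were not called (8 adjusted over the list alone), the enzyme gene AKR1C3 most at -0.88. This list's camera adjusted p was 0.000105, and adjusted p = 0.0701 with an estimated correlation. Of 16 Wnt, TGF-beta and BMP feedback genes 9 fell and 1 rose (9 and 2 adjusted over the list alone), with ID1 at -1.20 and ID3 at -1.15 (camera adjusted p = 0.000558, and adjusted p = 0.0701 with an estimated correlation). Interferon response genes had 11 of 22 falling and 2 rising (14 and 2 adjusted over the list alone), with OAS1 at -0.86 and MX1 at -0.61 and HERC5 up by 0.90. Their camera adjusted p was 0.0273, then adjusted p = 0.53 with an estimated correlation, and without DHT replicate 3 the list's mean log2 change went from -0.372 to -0.161 (adjusted p = 0.149). Among 19 epithelial junction genes 7 fell and 1 rose (the same counts adjusted over the list alone), CLDN1 at -0.87 (2 of 3 arrays labelled DHT with dox above background) and JUP at -0.51 (camera adjusted p = 0.0393, and adjusted p = 0.169 with an estimated correlation). That call was lost without DHT replicate 3, DHT with dox replicate 2 or DHT with dox replicate 3, at adjusted p of 0.0613, 0.0717 and 0.0588. Across the 5460 genes called for the average dox effect, the dox changes without and with DHT, which share no array, correlated at 0.937 (a description across genes, which are not independent replicates). Choosing genes by the average of both changes favours agreement, and all 12118 genes tested gave 0.862. Androgen-induced genes had 5 of 26 rising and 11 falling, the same counts over the list alone, and did not pass camera (adjusted p = 0.0708). The RUNX2 list had 1 of 15 rising and 4 falling (2 and 4 adjusted over the list alone), with a median of 0.024, a mean of -0.008 and camera pointing down (adjusted p = 0.865).

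**Figure D2:**
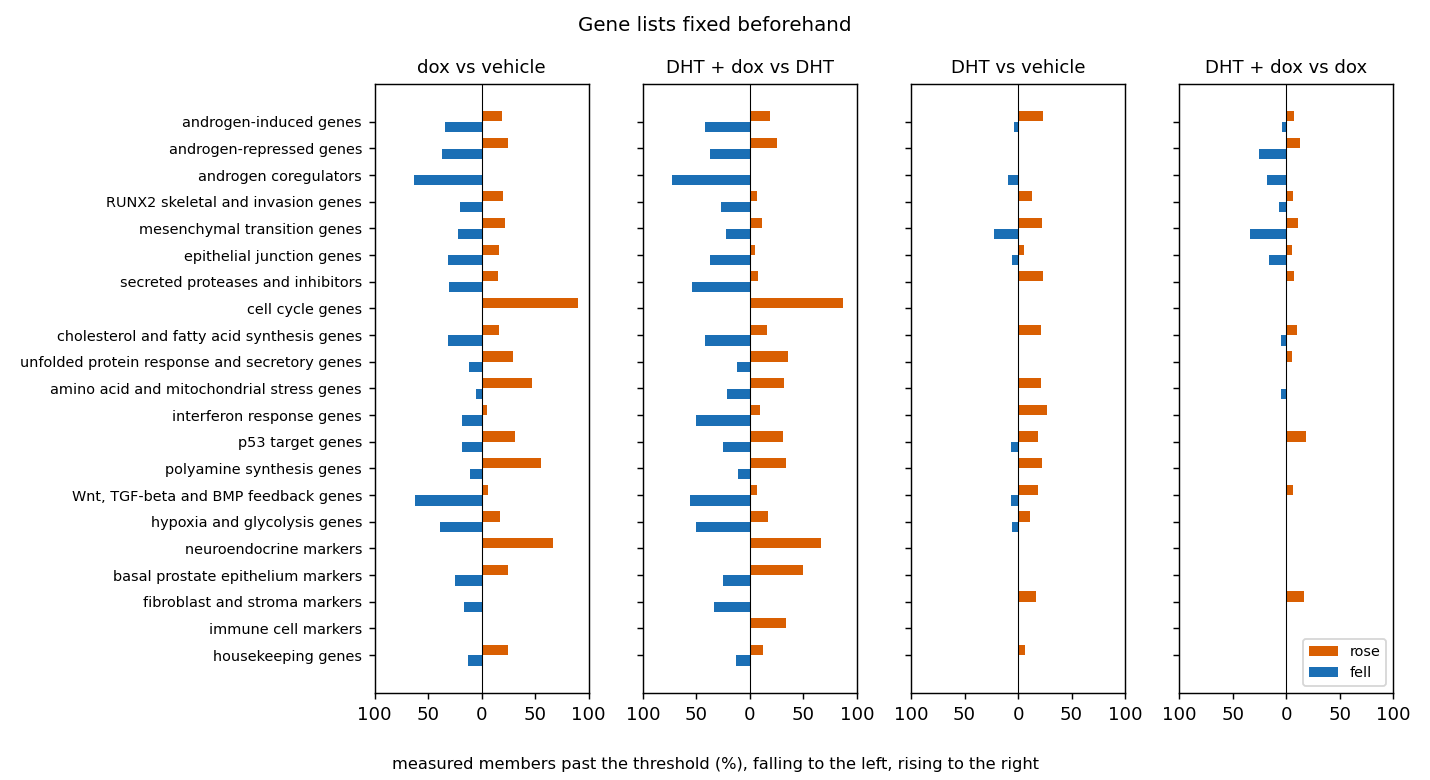
Share of the measured members of each gene list fixed beforehand that rose (to the right) or fell (to the left) past limma's adjusted p of 0.05, in percent, for 4 comparisons of 3 arrays against 3. Cell cycle genes rose in both comparisons of arrays with and without the dox label, and none was called by limma in either DHT comparison (9 and 3 of 31 at an unadjusted p under 0.05).

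DHT against vehicle asks what androgen treatment changes on arrays without the dox label. BZW2, a regulator of translation, was 2.52-fold higher on the arrays labelled DHT (log2 1.33 ± 0.08 SE, n = 3 per group, limma adjusted p = 1.59e-09), at 4614 against 1837. ALDH1A3, which makes retinoic acid, was 2.50-fold higher, EPAS1 2.27-fold, PLEKHS1 2.16-fold and DIO2, which activates thyroid hormone, 2.10-fold. PHLDA1 and TNFRSF21 were both 2.06-fold higher, RASD1 2.01-fold and TGFBI, a matrix protein gene induced by TGF-beta, 2.00-fold. IFIT1, an interferon-induced gene, was 2.28-fold higher (SE 0.31 on the log2 scale, limma adjusted p = 0.0228). Its call was lost without vehicle replicate 2 (1.06, adjusted p = 0.09), with only the groups compared (adjusted p = 0.0532), and with the mean of its probes (0.63, adjusted p = 0.0792). IGFBP5 was 2.47-fold lower, at 1962 against 4858, and the small nucleolar RNA gene SNORD16 was 2.31-fold lower. The secretory genes TFF3 (2.30-fold) and MUCL1 (1.89-fold) were lower, as were the carbonic anhydrase gene CA2 (1.82-fold), POFUT1 (1.80-fold), SYBU (1.79-fold), SELENBP1 (1.78-fold) and FKBP14 (1.77-fold). A probe for 28S ribosomal RNA, RNA28SN5, was 2.11-fold lower.

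The test passed 922 genes, 546 higher and 376 lower, and 114 of them changed at least 1.5-fold. Without vehicle replicate 3, DHT replicate 1 or DHT replicate 2 the number was 555, 552 and 607. Of 26 androgen-induced genes 6 rose and 1 fell (7 and 1 adjusted over the list alone), led by ALDH1A3 (1.32), TMPRSS2 (0.83) and SLC45A3 (0.43). This list's camera adjusted p was 0.0572, and adjusted p = 0.294 with an estimated correlation. FKBP5 was at -0.17 ± 0.09 (limma adjusted p = 0.265) and KLK3 was not above background. Of 8 androgen-repressed genes limma called 0 (1 at an unadjusted p under 0.05). Of 11 members of the coregulator list SPDEF changed by -0.32, a call lost without vehicle replicate 2 (-0.31), vehicle replicate 3 (-0.24) or DHT replicate 2 (-0.24). Interferon response genes passed camera (adjusted p = 1.32e-05), with 6 of 22 rising and 16 not called (12 adjusted over the list alone), among them ISG15 (0.90), OAS1 (0.67) and OAS3 (0.61). With an estimated correlation the list gave adjusted p = 0.354, and without DHT replicate 3 its mean log2 change went from 0.377 to 0.166 (adjusted p = 0.0179). Of 15 RUNX2 skeletal and invasion genes 2 rose (2 adjusted over the list alone), SMAD3 (0.58) and RUNX1 (0.41), with a list median of -0.049 and a mean of 0.03. RUNX1 lost its call without vehicle replicate 1 (0.36), vehicle replicate 3 (0.36), DHT replicate 1 (0.36) or DHT replicate 3 (0.33). SNAI2 rose by 0.47 by its brightest probe, and CLDN1, a tight junction gene, by 0.85. The other SNAI2 probe changed by 0.27 and was not called in a fit of all named probes (limma adjusted p = 0.143). The stress list had 4 of 19 rising (7 rising and 2 falling adjusted over the list alone), led by SLC7A5 (0.42). The p53 list had 3 of 16 rising, led by the cytokine gene GDF15 (0.54), and ZMAT3 at -0.54, which was 0.07 with the mean of its probes (the same counts adjusted over the list alone). Cell cycle genes had 0 of 31 called by limma, with 9 at an unadjusted p under 0.05. Neither they nor the other lists fixed beforehand passed camera, and the mesenchymal (-0.037 and 0.054) and Wnt lists (-0.002 and 0.028) had a median and mean of opposite sign.

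DHT with dox against dox is the matching comparison among arrays with the dox label. BZW2 was 2.45-fold higher (log2 1.29 ± 0.08 SE, n = 3 per group, limma adjusted p = 3.15e-09), DIO2 2.00-fold, the carbonic anhydrase gene CA12 1.98-fold and the netrin gene NTN4 1.95-fold. TGFBI (1.84-fold), ARF3 (1.78-fold), CLIC3 (1.75-fold), TNFRSF21 (1.73-fold), ALDH1A3 (1.69-fold) and the small heat shock gene HSPB8 (1.67-fold) followed. SNORD16 was 2.52-fold lower, IGFBP5 2.30-fold, TFF3 2.05-fold, KLK11 2.01-fold and ELAPOR1 1.89-fold. ST6GALNAC2, SEPTIN5, AGR3, MUCL1 and PLLP were between 1.64-fold and 1.67-fold lower. RNA28SN5 stood at 1160 against 1142. The test passed 518 genes, 247 higher and 271 lower, and 45 changed at least 1.5-fold. Leaving out 1 array of the comparison gave 329, 298 and 253 genes without dox replicates 1, 2 and 3, and 325, 336 and 279 without DHT with dox replicates 1, 2 and 3. Of 26 androgen-induced genes 2 rose, ALDH1A3 (0.76) and TMPRSS2 (0.45), and SGK1 changed by -0.55 (2 and 2 adjusted over the list alone). FKBP5 was at -0.09 (limma adjusted p = 0.624) and SNAI2 at 0.09 (limma adjusted p = 0.592). Among 9 mesenchymal transition genes 1 rose and 3 fell (2 and 3 adjusted over the list alone), with TGFBI at 0.88 and CD44 at -0.35. Among 11 members of the coregulator list AKR1C3 changed by -0.53 and SPDEF by -0.45. Of 19 cholesterol and fatty acid synthesis genes MVD (0.59) and FDPS (0.44) rose and 1 fell (2 and 2 adjusted over the list alone). No list fixed beforehand passed camera, and the lowest adjusted p was 0.0836, for p53 targets (3 of 16 rising, 6 rising and 1 falling adjusted over the list alone).

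Across the 1606 genes called for the average DHT effect (834 higher and 772 lower), the DHT change with dox followed that without dox, with Pearson's r of 0.804 and Spearman's rho of 0.728 and the same sign for 98.3% of genes. The genes were chosen by the average of both changes, which favours a like sign. Chosen by DHT against vehicle alone, 922 genes gave r of 0.741 and the same sign for 87.2%, and all 12118 genes gave 0.466. The median absolute log2 change of these 922 genes was 0.356 without dox and 0.17 with it. The 34 measured genes of both androgen lists gave r of 0.739 and rho of 0.619. These correlations describe genes, which are not independent replicates.

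**Figure D3:**
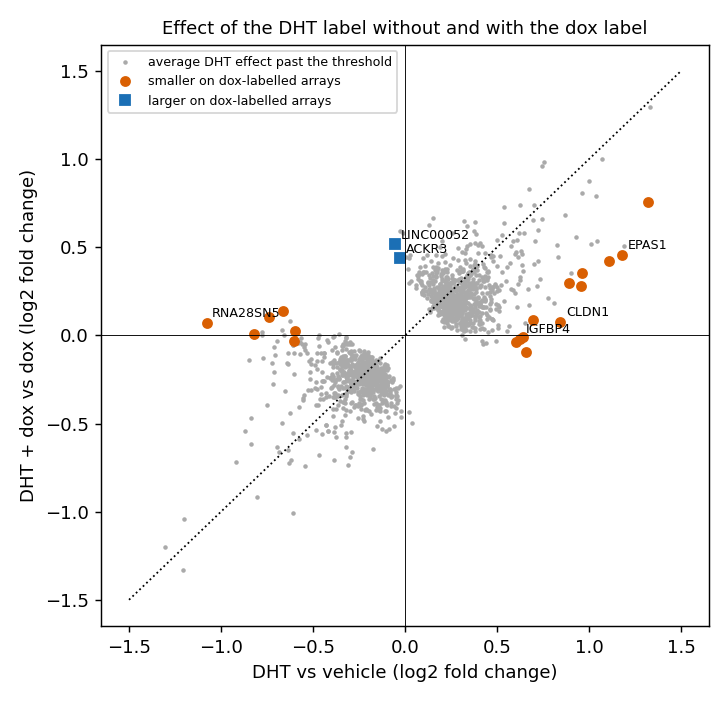
Log2 fold change of DHT with dox against dox (vertical) over that of DHT against vehicle (horizontal) for the 1606 genes called for the average DHT effect, with a dotted line of equality. Orange points mark the 18 genes whose DHT change was smaller or turned on arrays with the dox label, and blue squares the 2 whose change was larger.

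DHT with dox against vehicle asks what both treatments change together. GREB1 was 13.7-fold higher (log2 3.78 ± 0.10 SE, n = 3 per group, limma adjusted p = 8.93e-17), MGP 6.51-fold, PRSS23 5.85-fold, HSPB8 4.31-fold and SLC7A5 3.88-fold. UPK1A was 6.92-fold lower, BCAS1 4.98-fold, the autophagy gene DRAM1 3.70-fold, the cell cycle kinase gene CDK6 3.20-fold, CA5B 3.17-fold and SELENBP1 3.13-fold. TMPRSS2 was 1.62-fold lower and RUNX2 1.41-fold higher (limma adjusted p = 0.000578), though 0.20 on the log2 scale with the mean of both probes (adjusted p = 0.0609). The test passed 4459 genes, 2012 higher and 2447 lower, and 835 changed at least 1.5-fold. Cell cycle genes had 28 of 31 rising (29 adjusted over the list alone, camera adjusted p = 1.72e-12, and 0.00787 with an estimated correlation). The coregulator list (7 of 11 falling, as over the list alone, AKR1C3 at -0.97) and Wnt, TGF-beta and BMP feedback genes (10 of 16 falling and 1 rising, ID1 at -1.14) both passed camera at adjusted p of 0.000377. Polyamine (6 rising and 1 falling of 9), stress (7 and 3 of 19) and unfolded protein response genes (7 and 1 of 17, SDF2L1 up by 0.82) passed at 0.0289. Adjusted over the list alone these counts were the same, except for 2 rising Wnt, TGF-beta and BMP feedback genes. All 5 lists gave adjusted p = 0.0731 with an estimated correlation.

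Whether dox changed the DHT response itself was tested as the interaction, which was meant to show if RUNX2 weakens or strengthens androgen-driven transcription. The response of EPAS1 to DHT was smaller on arrays labelled dox: it rose by 1.18 without dox and by 0.46 with it, an interaction of -0.72 ± 0.12 (SE, n = 3 per group, limma adjusted p = 0.0124). CLDN1 (-0.77), the uroplakin gene UPK3A (-0.75), PLEKHS1 (-0.69), VTCN1 (-0.68), LINC00930 (-0.65), IGFBP4 (-0.64), GLRX (-0.64) and ALDH1A3 (-0.56) also rose with DHT in the absence of dox and had a negative interaction, and of these limma called a rise in its presence for PLEKHS1 (0.42) and ALDH1A3 (0.76) alone (adjusted p of 0.0654 or more for the others). Among genes that DHT lowered without dox, RNA28SN5 (1.15), the centrosome gene CEP19 (0.84), DUSP19 (0.83) and YRDC (0.80) had a positive interaction, and their changes with dox were 0.07, 0.10, 0.01 and 0.14 (limma adjusted p of 0.528 or more). The chemokine receptor gene CXCR4 was higher with DHT in the absence of dox (0.33) and changed by -0.38 in its presence (interaction -0.71). Among the 1606 genes called for the average DHT effect, LINC00052 (0.57) and ACKR3 (0.46) were the 2 called for a larger DHT change on arrays labelled dox, where ACKR3 read 2482 against 1832. In arrays without dox, the change of LINC00052 and ACKR3 with DHT was -0.05 and -0.03 (limma adjusted p of 0.785 and 0.883). UPK3A and LINC00930 were not above background on any array labelled dox, so the loss of their rise there is only a bound, and VTCN1 was above it on 1 of 3 arrays labelled dox alone. The interaction of TMPRSS2 was -0.38 (limma adjusted p = 0.256) and that of FKBP5 was 0.08 (limma adjusted p = 0.876).

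Many of these calls rested on single arrays or on 1 setting. EPAS1, CXCR4 and DUSP19 kept theirs in every alternative at the same threshold. CLDN1 (-1.66, adjusted p = 0.14) and UPK3A (-1.97, adjusted p = 0.0555) lost theirs after background subtraction only, CEP19 (0.33, adjusted p = 0.26) with the mean of its probes only, and IGFBP4 (-0.61, adjusted p = 0.058) without dox replicate 3 only. VTCN1 lost its call without dox replicate 3 (-0.67) or DHT replicate 2 (-0.66) and after background subtraction (-0.25). YRDC and PLEKHS1 lost theirs without vehicle replicate 2, dox replicate 1 or 3, or DHT replicate 1 or 2, YRDC also without vehicle replicate 3 and PLEKHS1 also without DHT with dox replicate 3, with limma adjusted p up to 0.0804 and 0.0843 in these fits. YRDC also lost its call with the mean of its probes (0.40, adjusted p = 0.103), and PLEKHS1 after background subtraction (-0.50, adjusted p = 0.502). Among the fits without 1 array, ALDH1A3 kept its call only without vehicle replicate 1, dox replicate 2 or DHT with dox replicate 1, and its adjusted p otherwise reached 0.121. In a fit of all named probes, the interaction of its brightest probe had a limma adjusted p of 0.0531. The other ALDH1A3 probe gave -0.73 there (limma adjusted p = 0.0141). GLRX kept its call only without vehicle replicate 1 or 2, dox replicate 2, DHT replicate 3 or DHT with dox replicate 1 (adjusted p up to 0.109), and LINC00930 only without vehicle replicate 3 or DHT with dox replicate 1 (up to 0.125). RNA28SN5 kept it only without vehicle replicate 1, dox replicate 2 or DHT replicate 3 (up to 0.125), LINC00052 only without vehicle replicate 3, dox replicate 2, DHT replicate 3 or DHT with dox replicate 1 (up to 0.118), and ACKR3 only without vehicle replicate 1 or DHT with dox replicate 2 (up to 0.0907). Background subtraction also ended the calls of ALDH1A3 (-0.46, adjusted p = 0.249), GLRX (-0.81, 0.0815), LINC00930 (-1.19, 0.232), RNA28SN5 (1.32, 0.0682) and LINC00052 (0.72, 0.14). The mean of a gene's probes ended those of RNA28SN5 (0.92, adjusted p = 0.0846) and LINC00052 (0.43, 0.103), and a fit without a trend in the prior variance those of ALDH1A3, RNA28SN5 and ACKR3 (adjusted p of 0.0674, 0.0895 and 0.0994).

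In all, 35 genes passed the interaction test, 16 positive and 19 negative, and 20 of them were among the 1606 genes called for the average DHT effect. Of these 20, 18 had a DHT effect that dox made smaller, 12 of them rising and 6 falling with DHT, and 2 had one that it made larger. Adjusted over the list alone, the numbers were 40 and 14. The amino acid and mitochondrial stress list (0 of 19 members called by limma, 4 at an unadjusted p under 0.05) and the interferon list (0 of 22, 7 unadjusted) passed camera downward, both at adjusted p of 0.00383, and gave adjusted p = 0.0901 and 0.513 with an estimated correlation. The interferon call was lost without DHT replicate 3 (adjusted p = 0.388). The number of interaction calls was 9 without dox replicate 3, 14 without DHT replicate 2, 16 without dox replicate 1 or DHT replicate 1, 17 without vehicle replicate 2, and 18 and 21 without DHT with dox replicates 3 and 2. The 18 smaller effects became 35 without vehicle replicate 1, 11 without vehicle replicate 2, dox replicate 1 or DHT with dox replicate 3, 10 without DHT replicate 1 or 2, and 6 without dox replicate 3. The 2 larger effects became 4 without vehicle replicate 3, 1 without dox replicate 2 or DHT with dox replicate 1 or 2, and 0 without vehicle replicate 2, dox replicate 1 or 3, DHT replicate 1 or 2, or DHT with dox replicate 3.

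**Figure D4:**
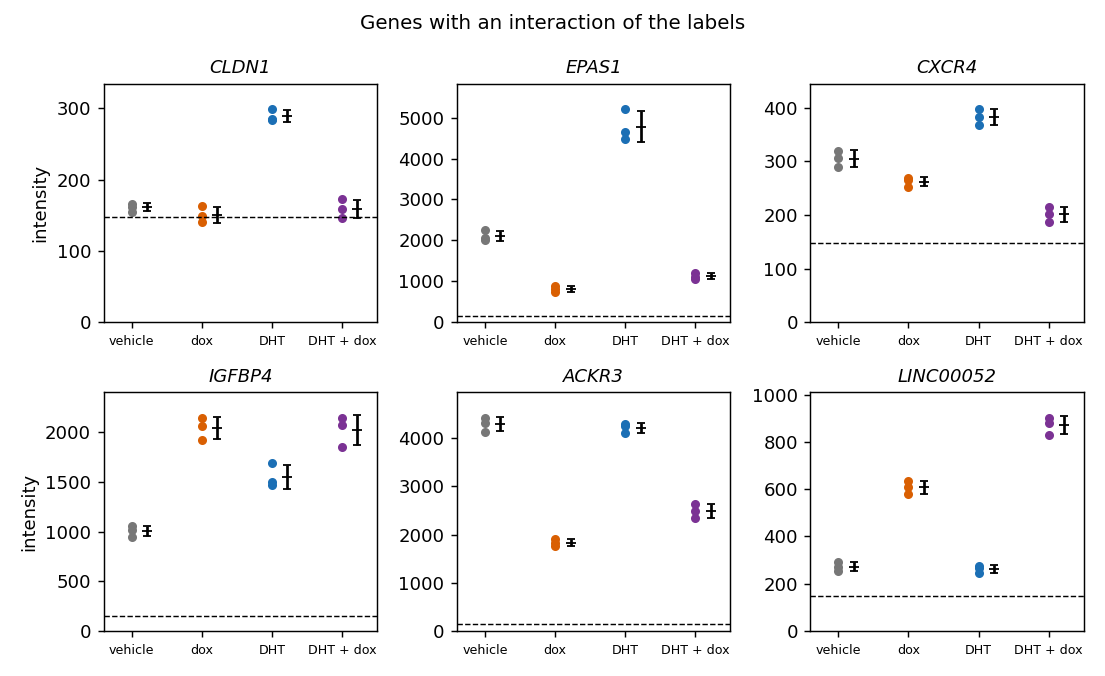
Intensity on each array (points, coloured by label) for 6 genes called for the interaction, with the mean and SD of each group of 3 beside the points and a dashed line at the background limit of 147.6. EPAS1 averages 2103 on vehicle and 4777 on DHT arrays, but 816.5 and 1121 on the arrays that also carry the dox label.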

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

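The tests of explanations in this part (probe pairs, marker levels, RUNX2 probes, estrogen lists, stress list, ribosomal RNA probe and the other splits of the arrays) were chosen only after the results had been seen. Directions below rest on the labels, which the RUNX2 probes and the lineage genes go against or leave unchecked.

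A difference between the DHT responses without and with the dox label drew attention to 35 genes that passed limma's interaction test. Among the named ones, the interaction on the log2 scale was negative for CLDN1 (-0.77), UPK3A (-0.75), EPAS1 (-0.72), CXCR4 (-0.71), PLEKHS1 (-0.69), VTCN1 (-0.68), LINC00930 (-0.65), and GLRX, IGFBP4 and PPP2R1B (-0.64 each). It was positive for RNA28SN5 (1.15), BMS1P1 (0.89), CEP19 (0.84), DUSP19 (0.83), YRDC (0.80), ZMAT3 (0.76), ZNF69 (0.75), ITPK1-AS1 (0.65), PATE1 (0.64), TENM4 (0.63), LINC00052 (0.57) and ACKR3 (0.46). The count was 9 without dox replicate 3, 14 without DHT replicate 2, 16 without dox replicate 1 or DHT replicate 1, 17 without vehicle replicate 2, and 18 and 21 without DHT with dox replicates 3 and 2. Of the genes not taken up above, BMS1P1 lost its call without dox replicate 3 (limma adjusted p = 0.058) or DHT replicate 1 (limma adjusted p = 0.0511). ZNF69 lost it without vehicle replicate 3, dox replicate 1 or 3, DHT replicate 1 or 2, or DHT with dox replicate 3 (adjusted p up to 0.0777), and with the mean of its probes (0.46, adjusted p = 0.214). PPP2R1B lost it without vehicle replicate 2, dox replicate 1 or 3, DHT replicate 1 or 2, or DHT with dox replicate 2 or 3 (up to 0.08). Among the fits without 1 array, ZMAT3 kept its call only without vehicle replicate 1, dox replicate 2 or DHT with dox replicate 1 (up to 0.161), and ITPK1-AS1 only without vehicle replicate 1, dox replicate 2 or DHT replicate 3 (up to 0.161). TENM4 kept it only without dox replicate 2, DHT replicate 1 or DHT with dox replicate 3 (up to 0.121), and PATE1 only without vehicle replicate 1 or DHT with dox replicate 2 (up to 0.115). The mean of its probes took ZMAT3 to 0.19 (adjusted p = 0.501). ZMAT3 and ITPK1-AS1 also lost their calls with every probe tested, array weights, background subtraction or no trend in the prior variance (up to 0.121 for both), and ITPK1-AS1 with the mean of its probes, a stricter filter on dim probes or an offset of 50 (up to 0.0941). Background subtraction ended the calls of TENM4 (1.20, adjusted p = 0.0654) and PATE1 (1.46, adjusted p = 0.316). PATE1 was above background on 0 arrays labelled dox or DHT alone, so its size is not measured there.

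Other assignments of the arrays were used to ask what chance alone gives. For the interaction, 2 of 100 reassignments gave as many genes, the real one included, with 35 genes against a highest other count of 46. That share is under 0.05 for the count as a whole, although 1 other reassignment gave more genes. It does not exclude chance for any single gene. For genes with a DHT effect made smaller by dox it was 1 of 100, with 18 genes against 0. For those made larger it was 2 of 100, with 2 genes against 21. Chance stays open for so small a count, since 1 other reassignment gave several times as many genes. Exchanging the dox labels in that reassignment would turn its 21 larger effects into smaller ones. That is more than the real 18, so chance is not excluded for the smaller effects either. So many genes in 1 reassignment may point to a structure of the samples that was not tested. For the average DHT effect it was 1 of 100, with 1606 genes against 173, and chance can be excluded. In each of the 5 comparisons of 3 arrays with 3, only the real split (1 of 10) gave as many genes, and the 10 splits are too few for a share under 0.05. The real counts were 3978, 922, 4068, 518 and 4459 (dox against vehicle, DHT against vehicle, and DHT with dox against DHT, dox and vehicle), and the highest other count was 0 each time.

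Most prostate luminal genes lay near background while most breast luminal genes were bright on every array. Probe identifiers displaced in the table would leave probes of a gene unrelated. Across 3227 genes the average dox effect of pairs of probes correlated at 0.801 and the average DHT effect at 0.578, which argues against displaced identifiers. A few arrays of other cells are argued against as well, since ESR1, GATA3 and TFF1 were each above the limit on all 12 arrays. The levels are consistent with cells of luminal breast type on every array, with 12 of 14 breast markers above the limit throughout against 3 of 18 prostate markers, although 7 of the 14 (FOXA1, XBP1, AGR2, TFF3, SPDEF, KRT8 and KRT19) are also expressed in prostate epithelium. The breast markers SCGB2A2 and ANKRD30A were above the limit on 0 arrays. Near the limit lay the breast marker TBX3 (153.5 to 228.3) and the prostate marker MSMB (164.7 to 215.8). The other prostate markers above the limit throughout were PMEPA1 (963.4 to 2077.6) and SLC45A3 (263.7 to 379.5). Whether the arrays, the cells or the labels were exchanged stays open, since no array of a known line was part of the series.

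Estrogen-regulated genes moved on the arrays labelled dox. Of 25 estrogen-induced genes not looked at when the list was written (CCND1, XBP1 and CTSD are also in lists fixed beforehand), 23 rose and limma called 0 lower in dox against vehicle. At an unadjusted p under 0.05 there were 24 in either direction, and 24 rose adjusted over the list alone (camera adjusted p = 5.38e-27, and 6.11e-06 with an estimated correlation). Of 14 estrogen-repressed genes 12 fell and 1 rose (the same counts adjusted over the list alone, camera adjusted p = 7.21e-09, and 0.00265 with an estimated correlation), so an estrogen response is a candidate explanation. RUNX2 induction stays open, because its brighter probe changed by only 0.08 in DHT with dox against DHT but the part of the transcript it reads is not known. Doxycycline itself stays open too. The amino acid and mitochondrial stress list gave camera adjusted p = 0.0489 in dox against vehicle but 0.169 in DHT with dox against DHT, both with an estimated correlation. That list does not read estrogen-regulated genes, so neither outcome could decide whether doxycycline moved them.

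Genes moved on the arrays labelled DHT, while most androgen-induced genes were not called. In DHT against vehicle 6 of 26 measured androgen-induced genes rose, against 546 of all 12118 genes tested, and an androgen response cannot be told apart from others here while the identity of the cells is in doubt. RUNX2 induction stays open, because the brighter RUNX2 probe changed by 0.41 in DHT against vehicle and 0.17 in DHT with dox against dox and what it reads is not known. Ribosomal RNA carried into the samples is argued against as the whole cause by the arrays labelled dox. Its probe changed by -1.08 in DHT against vehicle, but with an interaction of 1.15 this fall was absent in DHT with dox against dox. Of the 922 genes called in DHT against vehicle, 87.2% kept their sign there. Their median absolute log2 change was 0.356 without dox and 0.17 with it. Choosing them by the change without dox favours a larger value there, so this drop in size does not decide the question. Within groups, the mean of 920 of these genes (signed by their DHT change) had a slope of -0.055 on the probe (95% interval -0.093 to -0.017), where the DHT change needs -0.376. Without any 1 array the interval reached -0.127 at most. This slope cannot decide the question, since measurement error in 1 probe pulls it toward 0, and a part in the change stays open.

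Probes without a gene name, which enter no comparison of genes, also held signal. Of 5567 such probes above background, limma called 565 in dox against vehicle (301 higher and 264 lower) and 63 in DHT against vehicle (27 higher and 36 lower).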

How the results depend on the processing

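Of the settings given here, background subtraction alone was chosen after the data had been seen. Of 436 pairs of a named gene and a comparison past the threshold, 346 kept their direction and call in every alternative at the same threshold, 90 lost the call in at least 1, and 1 reversed: ZMAT3 in DHT against vehicle was 0.07 with the mean of its probes and -0.54 with its brightest probe alone. Quantile normalization applied again, arrays shifted to a common median and a floor of 10 moved no count by more than 1 gene, since the quantiles already matched and 0 values lay under the floor, so they test nothing. Without a trend in the prior variance 1 gene had a DHT effect made larger by dox, and the cause was not tested. With background subtracted the interaction count was 18, with 7 effects made smaller and 1 made larger by dox, and the cause was not tested. Requiring a change of at least 1.5-fold left 733 genes in dox against vehicle, 114 in DHT against vehicle, and 746, 45 and 835 in DHT with dox against DHT, dox and vehicle. It also left 47 for the average DHT effect and 0 made larger. At an adjusted p under 0.01, 400 genes remained past limma's threshold in DHT against vehicle, 180 in DHT with dox against dox and 711 for the average DHT effect, with 0 for the interaction (1220 at an unadjusted p under 0.05) and 0 made smaller or larger. Stricter thresholds by themselves give fewer calls, but not to the same extent: 2711 genes remained in dox against vehicle at an adjusted p under 0.01. All 35 interaction calls thus had a limma adjusted p between 0.01 and 0.05. Choosing androgen-responsive genes by DHT against vehicle gave 0 made larger and a correlation of 0.741 in place of 0.804, and choosing by either DHT comparison gave 10 made larger, as the choice sets which genes can be counted. Of the list tests, 19 passed camera, 4 with an estimated correlation, 58 with fry, which asks another question, and 24 with no filter on dim probes.

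Leaving out 1 array at a time gave 552 to 922 genes in DHT against vehicle, 253 to 538 in DHT with dox against dox, and 9 to 52 for the interaction, with 6 to 35 made smaller and 0 to 4 made larger by dox. Fewer arrays give fewer calls, but the cause of the rises above the full count was not tested. Within 1.5 times stayed dox against vehicle (3365 to 4006), DHT with dox against DHT (3456 to 4077) and vehicle (3809 to 4464), the average DHT effect (1208 to 1532) and the lists (16 to 25). The correlation ranged from 0.769 to 0.818 (jackknife error 0.042).

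Replicate numbers did not pair the arrays: deviations from the group means correlated over 0.1 in 1 of 18 same-numbered pairs (-0.121 to 0.208) and in 3 of 36 others. With the replicate block the counts were 3861, 886, 3991, 450 and 4411 (dox against vehicle, DHT against vehicle, and DHT with dox against DHT, dox and vehicle), 50 for the interaction, 1524 for the average DHT effect, 26 made smaller and 3 made larger, with a correlation of 0.794 and 19 list calls. The block ended 7 calls of named genes, at adjusted p of 0.05 or more, and no list call.

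Signal over background limits the rest. The intensities include background near 118.5, so folds of probes near the limit of 147.6 are understated, and 42.2% of probes were above it on each array.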

Other observations

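The added lists and the genes in this part were chosen only after the results had been seen. Of all 37 estrogen-induced genes, including those that drew attention, limma called 35 higher in dox against vehicle (36 adjusted over the list alone) and 35 in DHT with dox against DHT. In DHT against vehicle 7 rose and 3 fell, and in DHT with dox against dox 4 rose and 5 fell. Of the 25 not looked at when the list was written, 23 rose in DHT with dox against DHT (camera adjusted p = 1.98e-25, and 6.59e-06 with an estimated correlation), 3 rose in DHT against vehicle (adjusted p = 0.139), and 1 rose and 2 fell in DHT with dox against dox (adjusted p = 0.759). Of the 14 estrogen-repressed genes 12 fell and 1 rose in DHT with dox against DHT (camera adjusted p = 5.6e-09, and 0.00254 with an estimated correlation). In DHT against vehicle 2 of them rose and 2 fell (camera adjusted p = 0.2). In DHT with dox against dox 4 fell and limma called 0 higher, with 6 in either direction at an unadjusted p under 0.05 (camera adjusted p = 0.07).

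PGR, the progesterone receptor gene, averaged 128.1 on vehicle, 359.6 on dox, 115.0 on DHT and 291.6 on DHT with dox arrays, and was above background on all 6 arrays labelled dox and no others. TFF1 changed by 1.19 in dox against vehicle, -0.35 in DHT against vehicle and 1.63 in DHT with dox against DHT (interaction 0.44, limma adjusted p = 0.0927). ESR1 changed by -0.62 and -0.51 in the comparisons of arrays with and without the dox label. AGR3 was at 1.85 in dox against vehicle and -0.63 in DHT against vehicle, and TFF3 at 1.13 and -1.20. CXCL12 and PDZK1, not above background on the arrays labelled DHT, were at least 3.68-fold and at least 2.54-fold higher on those labelled DHT with dox.

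Breast luminal markers had 6 of 12 falling in DHT against vehicle (6 falling and 2 rising adjusted over the list alone, camera adjusted p = 0.00231, and 0.0306 with an estimated correlation), and 4 falling and 1 rising in DHT with dox against dox (adjusted p = 0.000573, and 0.018 with an estimated correlation). In dox against vehicle 4 rose and 5 fell, with a median of -0.071 and a mean of 0.101 (camera adjusted p = 0.681). Of 6 prostate luminal markers tested, 2 rose and 2 fell in dox against vehicle, and SLC45A3 alone rose in DHT against vehicle (0.43, list median -0.044, mean 0.057). Across the 1606 genes called for the average DHT effect, that effect correlated with the average dox effect at -0.145, and 49.7% had the same sign (a description across genes, which are not independent replicates).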
